A study of Mus musculus with 2 samples.

How the data were processed

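The series holds 2 samples of mouse (strain C57BL/6) leukaemia cells, 1 from vehicle-treated and 1 from brequinar-treated animals, sorted for GFP. Per the labels' protocols, RNA was poly(A)-selected and made into strand-preserving libraries, which were read as paired ends of 101 bases and processed with the Broad Picard pipeline. The deposited values are whole-number counts of reads per gene, not normalised. Per the submitters' processing notes, the tools used include STAR 2.4.2a and Picard 1.99 and 2.2.4, and the build was mm10. The role of each tool, the counting program, its strand setting and the annotation release are not given in the sources used here. For this reason, genes that overlap on either strand, and genes with near-identical copies, carry an uncertain share of reads. Each column of the deposited table was matched to its sample by name.

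The table has 45318 genes, given as Ensembl identifiers, and 4 closing lines of reads that name no gene (ambiguous, multimapping, without a feature, unmapped). Those lines held 21.6% of all reads in the vehicle library and 20.2% in the brequinar library and stayed out of library sizes and ratios. Multimapping reads alone made 7.39% and 6.92%, so genes with many copies can be undercounted by an unknown amount. Symbols and coordinates came from GENCODE mouse release 21, which uses GRCm38, the assembly that mm10 also names, by identifier without version. A symbol was found for 44671 identifiers. The unmatched identifiers held 0.0595% and 0.0480% of gene counts. The 50 most abundant genes held 15.0% and 15.8% of gene counts.

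Counts were scaled by TMM (edgeR 4.0.16, R 4.3.3), with factors of 1.03 for the vehicle and 0.969 for the brequinar library, and expressed as CPM. Against scaling by total counts alone, TMM shifted each log2 ratio by 0.092. The log2 ratio of brequinar over vehicle was computed with a prior count of 2. Genes with a mean of at least 1 CPM over both libraries entered (11504 genes). With 1 library per group no test between treatments is possible, so a fixed rule of size was used, in which a gene is called higher or lower at 2-fold or more. The exact (Clopper-Pearson) 95% interval of a gene's ratio, conditional on its summed count, covers counting error only. The floor for a count of 0 was set at 3 counts. Each list's median log2 ratio was placed among 10000 random lists of equal size, matched on mean CPM in 20 bins. Lists with fewer than 5 measured members got no percentile. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

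The comparison, its filters, 37 gene lists with 818 members and the alternatives were fixed before the data were examined, except where the text says otherwise. Of these members 3 were not found under their symbol (Hbb-b1, Hbb-b2 and Ahsp). The lists covered de novo pyrimidine synthesis, pyrimidine salvage, nucleotide and sugar metabolism, p53 targets, granule and neutrophil genes, monocyte and macrophage genes, MLL fusion targets, progenitor genes, ribosome and cell cycle genes, stress and interferon responses, antigen presentation, energy and sterol metabolism, markers of other blood and stromal cells, and sex-linked genes. Named genes followed a rule of 3 parts. The first took the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 5 CPM whose interval lay wholly beyond 2-fold, leaving out Gm, Rik and LOC symbols and pseudogenes. The second took up to 4 members of each list with the largest absolute log2 ratio, of which the text names at least 2 in that order, except for a few genes that are not reported here. The last part named Dhodh, Umps, Cad, Itgam, Ly6g, Mpo, Elane, Ltf, Hoxa9, Meis1, Kit, Cd34, Myc, Cdkn1a and Mki67 whatever their values. The pseudogene Gm10913 is named in the report outside this rule, chosen after its values were seen.

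Alternatives were other scalings (DESeq2 1.42.0 size factors, total counts, upper quartile, and totals without the 50 most abundant and the mitochondrial genes), other filters, prior counts of 0.5 and 5, thinning of the deeper library, other thresholds, unmatched random lists, 50 bins, and the mean in place of the median. A lowess correction for transcript length and GC content (span 0.3) and a count without markers of other cells were added after seeing the data. Length and GC content were those of each gene's longest annotated transcript. The procedure was tested on simulated counts drawn from the real means and library sizes with counting (Poisson) error only. No spread between animals or sorts was simulated, so the test cannot show how many calls such spread would give. Of 100 genes changed 4-fold, 100 were called in the right direction, of 100 changed 1.5-fold none was called, and no unchanged gene was called. The counting interval held the true ratio for 95.5% of 11506 genes. Of 100 unchanged lists 10 lay outside the central 95% of their random lists, and a larger test of 1000 such lists, with 1000 random lists each, placed 34 outside. Leaving out a replicate was not possible with 1 library per group.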

Results

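Gene expression was measured by poly(A)-selected RNA sequencing in mouse leukaemia cells that carry MLL/AF9, a fusion oncogene of acute myeloid leukaemia. Leukaemic mice had received either vehicle or brequinar, a small molecule that inhibits dihydroorotate dehydrogenase, the mitochondrial enzyme of de novo pyrimidine synthesis. GFP-positive leukaemia cells were then sorted from bone marrow. There were 2 libraries, 1 per treatment, so no difference below has a replicate check and none has a p-value. The gene counts summed to 47935476 in the vehicle library and 47950714 in the brequinar library. A count was detected for 19742 and 19322 genes, respectively. A single count was worth 0.0202 and 0.0215 CPM (counts scaled to library size), and a count of 0 allowed up to 0.0606 and 0.0646 CPM (3 counts). Dose, treatment time and the number of animals behind each library are not given in the sources used here.

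The comparison asked how gene expression in leukaemia cells from a brequinar-treated marrow differed from that in cells from a vehicle-treated one. Genes of late neutrophil granules and of neutrophil chemotaxis were higher in the brequinar library, and several genes of immature progenitors, together with Mpo (myeloperoxidase, the main enzyme of primary granules), were lower. Of 32 measured genes of secondary and tertiary granules and maturing neutrophils, 29 were at least 2-fold higher. Of 29 measured p53 target genes, 17 were at least 2-fold higher, led by Phlda3, a p53-induced repressor of Akt, and by Cdkn1a, which encodes the cell cycle inhibitor p21. Of 23 genes of cholesterol synthesis, 10 were at least 2-fold lower. Markers of erythroid cells and of some macrophages were also higher in the brequinar library.

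Among 11504 genes with a mean of at least 1 CPM over both libraries, 742 (6.45%) were at least 2-fold higher in the brequinar library, 506 (4.40%) were at least 2-fold lower, and 10256 lay within 2-fold. At least 8-fold differences were found for 100 genes on the higher side and 31 on the lower side. With scaling by total counts alone the split was nearly even (662 higher, 632 lower), and 600 higher and 288 lower genes had their whole counting interval beyond 2-fold. Calls use the log2 ratio with a prior count of 2, which draws low genes slightly towards 0. Values given in pairs below are normalised CPM in the vehicle library and then in the brequinar library. Intervals are exact 95% intervals that cover counting error only, since each group holds 1 library. Amplified reads without molecular identifiers are not independent molecules, so the intervals can be too narrow even for counting error. Each list of genes is also placed by its median log2 ratio (brequinar over vehicle) among 10000 random lists of equal size and matched expression, as a description of these libraries. Of 34 lists so placed, 12 lay above the central 95% of their random lists and 6 below it. Lists of independently drawn genes would give 1.7 in all. Members of these lists can vary together and some are shared, so 1.7 is no measure of chance between animals.

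**Figure D1:**
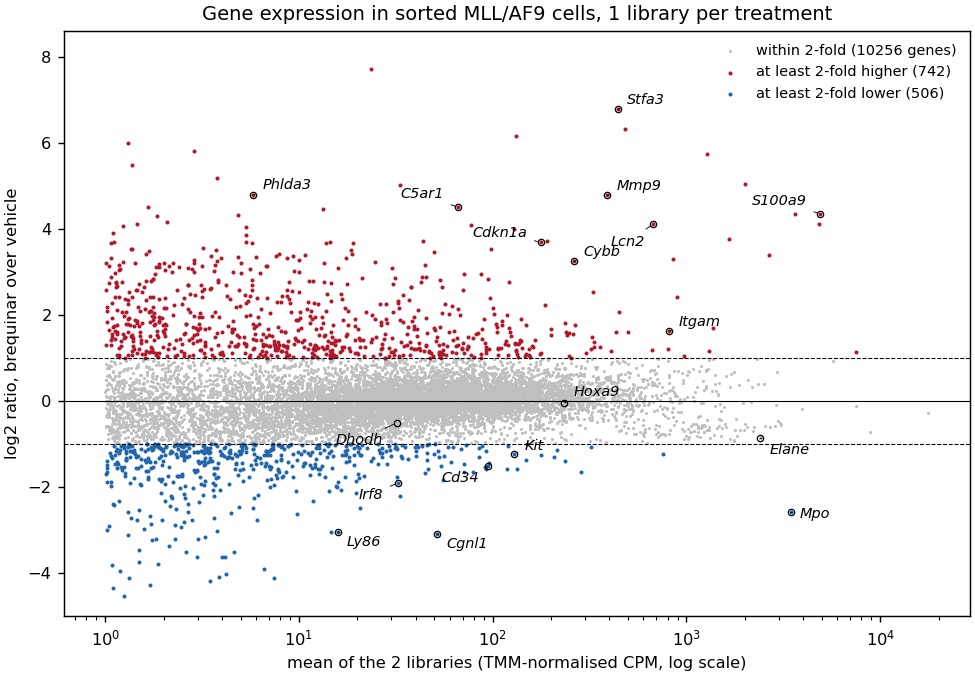
Log2 ratio of brequinar over vehicle against the mean normalised CPM of both libraries (log scale), 1 point per gene for 11504 genes. Red points (742) are at least 2-fold higher and blue points (506) at least 2-fold lower in the brequinar library, dashed lines mark 2-fold, and circled genes are labelled. Stfa3, Mmp9 and S100a9 lie far above the upper line, Mpo lies below the lower line, and Hoxa9 lies near 0.

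The genes of secondary and tertiary granules and maturing neutrophils had a median log2 ratio of 2.78 (percentile 100). The 4 members with the largest ratios were Stfa3 (7.96 and 882 CPM), Stfa2 (3.58 and 259.6 CPM), BC100530 (118 and 3881 CPM) and Mmp9 (27.3 and 753 CPM). Stfa3, Stfa2 and BC100530 belong to the stefin A family of cysteine protease inhibitors, and Mmp9 encodes a gelatinase stored in tertiary granules. Stfa3 (ENSMUSG00000054905.2) was 111-fold higher (interval 100.3 to 123), and Mmp9 (ENSMUSG00000017737.2) was 27.6-fold higher (interval 26.1 to 29.1). S100a9 and S100a8, whose products form calprotectin, stood at 459 and 9365 CPM and at 343 and 6945 CPM. Lcn2, an iron-sequestering protein of secondary granules, stood at 73.7 and 1277 CPM, and Ltf, which encodes lactoferrin, at 96.1 and 561 CPM. Itgam, which encodes the CD11b integrin, was 3.09-fold higher (399 and 1234 CPM), and Ly6g was 7.0-fold higher at a low level (2.97 and 20.8 CPM). Erythroid and macrophage markers, described further on, were higher in the same library.

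The stefin A genes lie side by side on chromosome 16 (GRCm38), with Stfa1 starting at 36276951 and Stfa3 ending at 36455392, Stfa1 on the plus strand and Stfa3 on the minus strand. Within this span and 100000 bases on each side, 9 of 9 genes with a mean of at least 1 CPM were at least 2-fold higher. The window was not fixed beforehand, and the 9 include stefin genes named for their high ratios. Stfa1 stood at 524 and 9151 CPM, and Stfa2l1, which lies upstream of this window at 36156811 to 36161953, stood at 11.8 and 952 CPM. These genes are near-identical copies. Multimapping reads were kept out of gene counts, so each copy can be undercounted by an unknown amount, and the share of reads that each holds is uncertain.

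**Figure D2:**
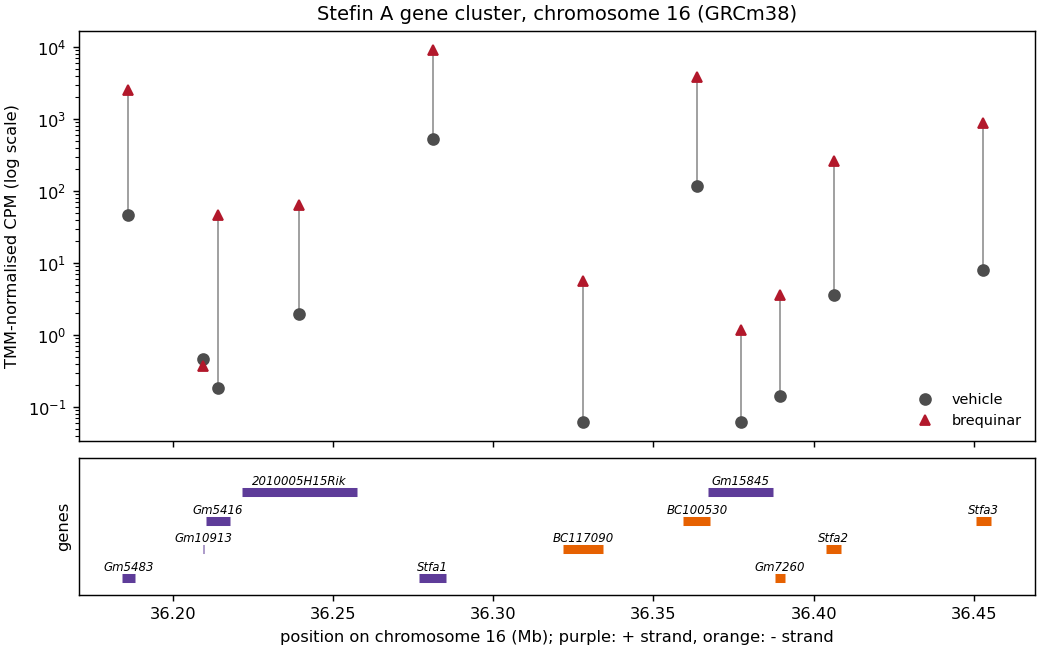
Normalised CPM (log scale) of the 11 genes with a count in the stefin A cluster, plotted by position on chromosome 16 (Mb, GRCm38), with the vehicle library as grey circles, the brequinar library as red triangles, and gene bodies below (purple, plus strand; orange, minus strand). The brequinar value exceeds the vehicle value at each gene except the pseudogene Gm10913, and Stfa1 is the most abundant.

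Genes of mature neutrophils and chemotaxis had a median log2 ratio of 1.5 (percentile 100), with 16 of 24 measured members higher and 2 lower. Slc2a3, a glucose transporter, stood at 6.10 and 81.5 CPM, and Fpr2, a receptor for formylated peptides, at 1.96 and 25.5 CPM. Il1rn, the interleukin 1 receptor antagonist, stood at 8.18 and 91.2 CPM. C5ar1, the receptor of the complement fragment C5a and among the 12 highest genes, was 22.8-fold higher (interval 20.2 to 25.9; 5.58 and 127 CPM). The NADPH oxidase and Fc receptor genes had a median of 0.72 (percentile 100), with 6 of 15 higher and none lower. They were led by Cybb, the catalytic subunit of the phagocyte oxidase (50.1 and 475 CPM), and Tlr2 (4.28 and 20.8 CPM). Ly6g5b was also among the 12 highest genes (1.11 and 25.6 CPM).

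Primary granule genes had a median log2 ratio of -0.65 (percentile 0). Mpo was the single member of 12 that was at least 2-fold lower, by 6.04-fold (interval 5.98 to 6.10; 5912 and 979 CPM). Gstm1 stood at 279 and 141 CPM, and Elane, which encodes neutrophil elastase, at 3098 and 1702 CPM. Progenitor and stem cell genes had a median of -0.35 (percentile 0.14), with 7 of 20 lower and 4 higher. This median was -0.14 without the filter on low genes and -0.59 among members with a mean of at least 5 CPM. The members with the largest absolute ratios were Tal1, which was higher at a low level (0.424 and 2.2 CPM), Sox4, which was lower (49.96 and 14.6 CPM), Hlf, which was higher (0.950 and 3.12 CPM), and Flt3, which was lower (4.49 and 1.44 CPM). Kit, the stem cell factor receptor, was 2.36-fold lower (interval 2.27 to 2.45; 180 and 76.5 CPM), and Cd34 was 2.87-fold lower (interval 2.74 to 3.01; 140 and 48.8 CPM).

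Target genes of MLL fusions had a median log2 ratio of -0.12 (percentile 8.16), with 2 of 24 higher and 3 lower. Flt3 was lower, and Mef2c (0.728 and 2.30 CPM) was higher. Hoxa9 and Meis1, central transcription factors of this leukaemia, stood at 238 and 231 CPM and at 71.6 and 87.4 CPM, both within 2-fold. Among myeloid transcription factors 4 of 18 were higher and 3 lower, with a median of 0.25 (percentile 97.92; 0.16 with total-count scaling). Id2 (5.19 and 22.4 CPM) and Gata1 (0.465 and 2.09 CPM), which is also among the erythroid markers, were higher. Irf8, a factor of monocyte and dendritic cell fate, was lower (51.5 and 13.8 CPM).

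The p53 target genes had a median log2 ratio of 1.13 (percentile 100), with none of the 29 members lower. Phlda3 was 30.9-fold higher (interval 19.4 to 52.5; 0.364 and 11.2 CPM), and Cdkn1a was 12.9-fold higher (interval 12.2 to 13.7; 25.5 and 330 CPM). Trp53cor1, the long noncoding RNA beside Cdkn1a, stood at 0.687 and 7.21 CPM, and the kinase gene Plk2 at 0.707 and 6.63 CPM. In the Bcl2 family, which controls mitochondrial cell death, the median was 0.38 (percentile 99.67) and the mean 0.24, with 2 of 14 higher and 1 lower. Bcl2a1d was higher (0.869 and 2.37 CPM), with near-identical copies that leave its level uncertain, Bcl2 was lower (9.05 and 3.60 CPM), and the p53 target Bax was higher (63.7 and 149 CPM).

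All 32 genes of G2 and mitosis had log2 ratios above 0, with a median of 0.59 (percentile 100), and none passed 2-fold. Aurka and Plk1, mitotic kinases, stood at 90.1 and 164 CPM and at 73.5 and 129 CPM, and the proliferation marker Mki67 at 498 and 707 CPM. The 35 genes of G1/S and replication had a median of 0.08 (percentile 56.24), whose sign turned with total-count scaling, and none passed 2-fold. The cyclin genes Ccne2 (53.4 and 103 CPM) and Ccne1 (14.1 and 24.2 CPM) had the largest ratios. Of 13 replication-dependent histone genes, which poly(A) selection captures poorly, 1 was higher (Hist1h2bc, 13.2 and 33.9 CPM) and 1 lower (Hist1h1a, 3.84 and 1.85 CPM), with a median of -0.08 (percentile 51.06), whose sign turned with the length and GC correction (0.21) and when the mean was taken (0.09).

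The inhibitor's own pathway showed no member past 2-fold. Among 7 genes of de novo pyrimidine synthesis the median log2 ratio was -0.06 (percentile 18.14). Dhodh, the gene of the inhibited enzyme, had the largest absolute ratio (37.5 and 26.3 CPM; 1.43-fold lower, interval 1.33 to 1.53). Cmpk1, a pyrimidine monophosphate kinase, stood at 175 and 235 CPM, Cad, which encodes the enzyme of the first steps, at 165 and 141 CPM, and Umps, which encodes the last enzyme of uridine monophosphate synthesis, at 156 and 150.2 CPM. In pyrimidine salvage, transport and breakdown 2 of 13 genes were higher and none lower, with a median of -0.02 (percentile 42.89) and a mean of 0.26, so the sign depended on the summary. They were Upp1, uridine phosphorylase (0.162 and 1.85 CPM), and Nt5e, the ectoenzyme CD73 (3.25 and 8.78 CPM). Upp1 had 8 counts in the vehicle library and a mean of 1.007 CPM, just above the filter. With total-count scaling 12 genes of this list passed the filter, with a median of -0.223. In dNTP and folate metabolism 1 of 14 was higher, with a median of 0.13 (percentile 71.62). That gene was Samhd1, a dNTP hydrolase (89.5 and 239 CPM), and Dck, which encodes deoxycytidine kinase, stood at 55.3 and 97.54 CPM. No gene was called among 17 of purine synthesis and salvage (median -0.07, percentile 6.71), where Impdh1 (4.99 and 2.48 CPM; 2.02-fold lower before the prior count) lay at the limit and Adssl1 stood at 204 and 142 CPM. None was called among 17 of UDP-sugar and O-GlcNAc metabolism (median 0.03, percentile 46.84, its sign turning with scaling), where Ugp2 stood at 124 and 225 CPM and Pgm3 at 26.5 and 19.4 CPM.

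Ribosomal protein genes were lower as a group by less than 2-fold. All 52 measured cytosolic ribosomal protein genes had log2 ratios below 0, with a median of -0.67 (percentile 0). Rps20 (1058 and 451 CPM) was the single member past 2-fold, and Rpl13a stood at 1323 and 716 CPM. Many processed pseudogenes copy these genes, so their absolute levels are uncertain. Myc and ribosome biogenesis genes had a median of -0.17 (percentile 0.02, and 2.68 against random lists not matched on expression) with none of 32 past 2-fold. The nucleolar protein gene Npm1 stood at 1402 and 899 CPM, Cdk4 at 332 and 226 CPM, and Myc itself at 118 and 97.52 CPM.

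Cholesterol synthesis genes had a median log2 ratio of -0.94 (percentile 0), with 22 of 23 below 0 and none higher. Sqle and Cyp51, enzymes of the sterol branch, stood at 69.4 and 23.3 CPM and at 79.8 and 28.0 CPM. Glycolysis genes had a median of 0.05 (percentile 42.71, its sign turning with total-count scaling), with 1 of 20 lower, Pfkl (119 and 57.4 CPM), beside Pfkm at 14.3 and 7.23 CPM. None of 32 nuclear-encoded respiratory chain genes passed 2-fold (median -0.05, percentile 2.51, and 0.03 after the length and GC correction), where Ndufa10 stood at 98.8 and 75.7 CPM and Uqcrb at 183 and 238 CPM. The 13 mitochondrially encoded mRNAs had a median of -0.43 (percentile 1.76), with 1 lower, mt-Nd3 (3.29 and 1.59 CPM), and mt-Nd4l at 1.39 and 0.840 CPM. Mitochondrially encoded genes held 1.62% of gene counts in the vehicle library and 1.35% in the brequinar library.

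The integrated stress response genes, which Atf4 controls, had a median log2 ratio of -0.14 (percentile 2.52), with 2 of 29 higher and 2 lower. Phgdh, an enzyme of serine synthesis, was lower (15.8 and 3.64 CPM), as was Stc2 (8.41 and 2.95 CPM), and Sesn2, also on the p53 list, was higher (7.52 and 17.6 CPM). Interferon-stimulated genes had a median of 0.79 (percentile 100), with 13 of 32 higher and 1 lower. Ifit3 (0.424 and 2.67 CPM), Gbp2 (21.2 and 87.9 CPM) and Zbp1 (9.62 and 38.3 CPM) were the highest by ratio. MHC class I presentation had a median of 0.38 (percentile 99.28; 0.16 over the 12 members with a mean of at least 5 CPM), with 3 of 14 higher, led by H2-Q7 (0.950 and 5.98 CPM), which has near-identical copies, and the transactivator gene Nlrc5 (10.8 and 29.8 CPM). MHC class II presentation had 4 of 9 higher and 2 lower (median 0.40, percentile 96.80; 0.71 over the 6 members with a mean of at least 5 CPM, and a mean log2 ratio of 0.24), while the summed level of all 9 was 171 and 123 CPM. H2-Eb1 (1.29 and 3.55 CPM) and H2-Aa (3.07 and 7.56 CPM) were higher, and H2-Oa (6.81 and 2.80 CPM) was lower. Immediate early and handling stress genes had 2 of 22 higher and 2 lower (median -0.03, percentile 20.43, and a mean of 0.03), with Nr4a1 higher (1.60 and 17.0 CPM) and the heat shock gene Hspa1a lower (3.54 and 1.53 CPM).

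Monocyte and macrophage genes had a median log2 ratio of 0.84 (percentile 100), with 13 of 29 higher and 2 lower. Over the 16 members with a mean of at least 5 CPM the median was 0.14, and the summed level of all 29 was 1582 and 1632 CPM. Mrc1, the mannose receptor, stood at 0.647 and 9.99 CPM, Treml4 at 0.243 and 3.01 CPM, the nuclear receptor gene Nr4a1 at 1.60 and 17.0 CPM, and C1qc, a complement component of tissue macrophages, at 0.950 and 9.15 CPM. Erythroid markers had a median of 2.31 (percentile 100), with 14 of 15 higher, led by Car1 (0.424 and 9.32 CPM) and Trim10 (0.222 and 2.17 CPM). Megakaryocyte and platelet genes were higher in 3 of 4 cases, with Cd9 at 14.9 and 94.2 CPM and Gp9 at 1.92 and 5.49 CPM. Markers of mast cells, basophils and eosinophils had a median of 0.39 (percentile 98.02), with 4 of 11 higher and 1 lower. Ccr3 was higher (0.465 and 3.98 CPM), and Prg3, an eosinophil granule gene, was lower (35.1 and 6.16 CPM). Among B and plasma cell markers 1 of 10 was higher, Vpreb1 (0.424 and 1.62 CPM), and 2 were lower, including Cd79b (26.2 and 9.86 CPM). Their median was 0.10 (percentile 78.78), and it turned negative among members with a mean of at least 5 CPM. The summed level of all 10 was 99.2 and 51.3 CPM. Among dendritic cell markers 1 of 6 was higher, Siglech (0.505 and 1.81 CPM), and 2 were lower, including Klk1 (2.28 and 0.344 CPM). Their median was -0.34 (percentile 29.09), its sign turning without a filter. Only 2 T and NK cell markers were measured, Lat (2.02 and 3.06 CPM) and Bcl11b (7.13 and 8.42 CPM), and 2 stromal and endothelial ones, Pecam1 (25.1 and 6.76 CPM) and Vcam1 (370 and 496 CPM).

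Among 5 sex-linked genes the median log2 ratio was 0.04 (percentile 49.12, its sign turning with scaling) and the mean was 0.62. The Y-linked genes Eif2s3y (0.384 and 2.5 CPM) and Ddx3y (0.626 and 2.2 CPM) were higher. Xist, the noncoding RNA of the inactive X chromosome, was lower (294 and 120 CPM).

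**Figure D3:**
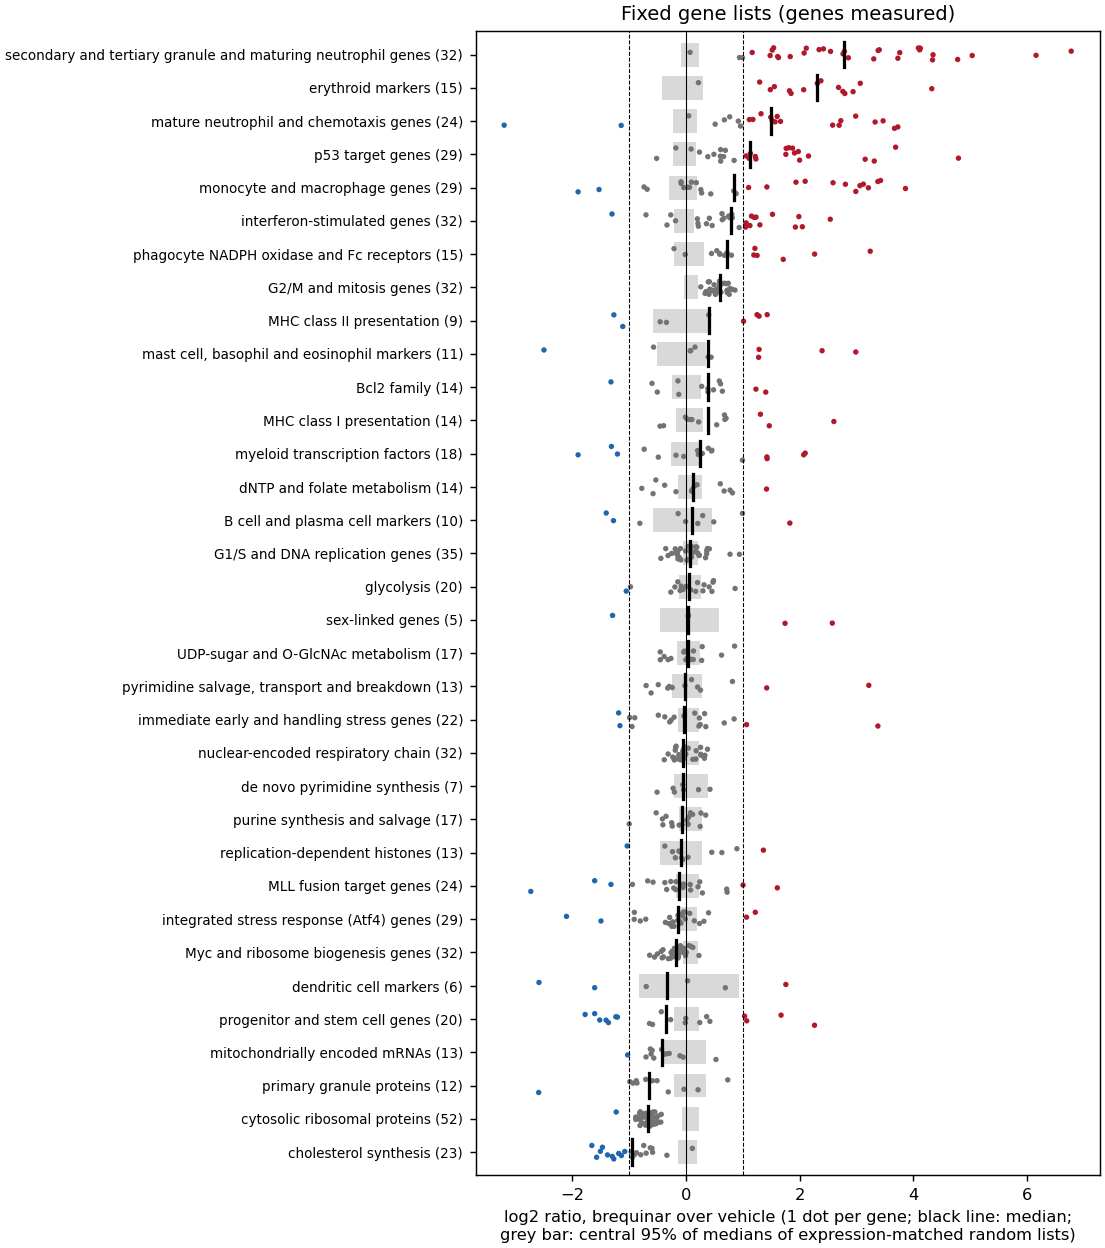
Log2 ratio of brequinar over vehicle for each measured member (1 dot per gene) of the 34 gene lists with at least 5 measured members, whose numbers stand in parentheses. Black lines are list medians, grey bars hold the central 95% of medians of matched random lists, dashed lines mark 2-fold, and red and blue dots are at least 2-fold higher and lower. The medians run from 2.78 for late neutrophil granule genes to -0.94 for cholesterol synthesis genes.

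The 12 lowest of the more abundant genes included Mpo and Prg3. The others were Kap (12.5 and 0.797 CPM), Cgnl1, a cell junction protein gene (92.2 and 10.8 CPM), Egln3, an oxygen-dependent prolyl hydroxylase of hypoxia-inducible factors (26.0 and 3.10 CPM), and Ly86, a partner of the receptor RP105 (28.3 and 3.38 CPM). Iqcg (10.6 and 1.53 CPM), the kinase gene Matk (16.9 and 2.67 CPM), the arginine synthesis gene Ass1 (9.88 and 1.72 CPM), the adaptor gene Lat2 (19.8 and 3.90 CPM), Epop (9.70 and 2.00 CPM) and Txndc5, a disulphide isomerase gene (55.0 and 11.8 CPM), completed them. Cgnl1 (ENSMUSG00000032232.11; chromosome 9, 71626509 to 71771602) was 8.54-fold lower, with an interval of 7.78 to 9.38. Mpo (ENSMUSG00000009350.10) lies on chromosome 11 from 87793581 to 87804413, Cdkn1a (ENSMUSG00000023067.10) on chromosome 17 from 29090976 to 29100727, and Dhodh (ENSMUSG00000031730.14) on chromosome 8 from 109591343 to 109608673. The difference between these libraries includes any difference between the animals and the sorts.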

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

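The length and GC correction, and the count without markers of other cells, were tests chosen after the result was seen. The numbers of genes called depended most on the filter and the threshold. Without a filter 2470 genes were higher and 2074 lower among 21287, and with a mean of at least 5 CPM 457 were higher and 230 lower among 9483, since fewer or more low genes entered. At 1.5-fold 1456 were higher and 1463 lower, and at 4-fold 258 and 82. Requiring the whole counting interval beyond 2-fold left 288 lower genes, and 600 higher ones. Under the 4 other scalings the counts lay between 662 and 736 for higher genes and between 510 and 632 for lower genes, and total counts alone gave 662 and 632. Without the lists of other cell types and sex-linked genes 704 were higher and 497 lower. Scaling by total counts moved the median log2 ratio of the ribosomal protein genes to -0.76, of the Myc and ribosome biogenesis genes to -0.26 and of the respiratory chain genes to -0.14. Totals without the 50 most abundant and the mitochondrial genes moved the ribosomal protein genes to -0.75 and the respiratory chain genes to -0.13, and the length and GC correction moved the ribosomal protein genes to -0.515. The cause of these shifts was not tested beyond the 0.092 by which TMM and total counts differ. Among the named genes past 2-fold and the lists outside the central 95%, none changed sign. Medians of several lists near 0 did. Pyrimidine salvage moved from -0.02 to between -0.295 without a filter and 0.071 after the length and GC correction, with a mean of 0.256, and the histones moved to 0.21 after that correction. The filter moved others: with a mean of at least 5 CPM the medians were 0.14 for monocyte and macrophage genes, 0.16 for MHC class I, 0.707 for MHC class II, -0.59 for progenitor and stem cell genes and -1.28 for B and plasma cell markers, and without a filter dendritic cell markers were at 0.07, MHC class II at 0.707 and progenitor and stem cell genes at -0.142. Of 106 named genes past 2-fold, between 102 and 106 stayed past it on the same side under each setting. The placement of 5 lists outside or inside the central 95% depended on the matching: Myc and ribosome biogenesis was at 0.02 and moved to 2.68 without matching, and lists near the limit were integrated stress response 2.42, respiratory chain 2.28 and mitochondrial mRNAs 5.01 with 50 bins, and MHC class II 98.33 without matching and 97.51 with 50 bins. Leave-one-out was not possible with 1 library per group. Genes with a few counts had wide intervals, such as Phlda3 with 18 counts in the vehicle library. No paired analysis was possible because each group holds 1 library.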

Other observations

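The families in this and the next paragraph, and their genes, were chosen after values were seen, and so were the tests below except those on marrow macrophage genes and transcript length. In the brequinar library 7 of 11 measured chemoattractant receptors were at least 2-fold higher and 4 lay within 2-fold. Of these, Fpr1, Fpr2 and Cxcr2 were on the chemotaxis list, and C5ar1 was among the highest genes. C5ar2, another receptor for C5a, stood at 1.62 and 9.82 CPM (vehicle, then brequinar), Gpr84, a receptor for medium-chain fatty acids, at 3.29 and 28.6 CPM, and Ptafr, the receptor for platelet-activating factor, at 12.1 and 41.2 CPM. Ccr2, which guides monocytes, stood at 29.2 and 30.4 CPM, and Cxcr4, which holds cells in the marrow, at 185 and 221 CPM. Of 9 genes of leukotriene and prostaglandin synthesis 3 were higher. Alox5, the first enzyme of leukotriene synthesis, was 16.15-fold higher (15.0 and 243 CPM), while its partner Alox5ap stood at 353 and 480 CPM and Lta4h, the next enzyme, at 916 and 942 CPM.

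Of 10 measured genes of fatty acid synthesis and desaturation 4 were at least 2-fold lower and 6 lay within 2-fold. The desaturase genes Scd2 and Fads1 stood at 432 and 138 CPM and at 24.9 and 6.26 CPM, and the elongase gene Elovl6 at 4.91 and 0.689 CPM. Fasn (276 and 199 CPM) and Acaca (93.1 and 76.9 CPM), which encode the enzymes that build the fatty acid chain, lay within 2-fold. Of 12 genes of haem and iron handling 5 were higher. Hmox1, haem oxygenase, stood at 6.37 and 54.3 CPM, and Slc40a1, the iron exporter, at 42.0 and 134 CPM. Slc40a1, Spic and Cd163 are also among the marrow macrophage genes tested below. The ferritin genes Fth1 (236 and 319 CPM) and Ftl1 (1116 and 1411 CPM) lay within 2-fold. For Xist, no shift of other X-linked genes was seen, with a median log2 ratio of -0.01 over 357 X-linked genes and 0.00 over 11126 autosomal genes. Genes silent on the inactive X would not shift with it, so this median cannot show what lowered Xist. The 4 X-linked genes known to escape inactivation had a median of 0.04.

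The first pattern is that late neutrophil granule genes were higher while Mpo, Kit and Cd34 were lower. Dilution of the sort by outside neutrophils would lower genes that only the leukaemia cells express as far as Kit. The 24 measured MLL fusion targets had a median log2 ratio of -0.12 (order-statistic interval -0.37 to 0.21). Whether neutrophils express some of these targets was not tested. Targets that they do express would fall less, so this median cannot exclude dilution. The pattern rested neither on the scaling nor on the stefin genes. The neutrophil list's median stayed at 2.69 or more under 4 other scalings and at 2.48 for the 28 members left without 4 stefin genes. Neither check could have brought the median under 2-fold. The scalings shifted ratios by at most 0.092, and 29 of 32 list members were at least 2-fold higher. RNA from outside neutrophils also stays open for the higher granule genes. All higher genes together gained 7.47% of the library. With total-count scaling the MLL fusion targets had a median of -0.21 (interval -0.47 to 0.12). If neutrophils lack these targets, that median allows a larger dilution of 13.4%, within limits of none and 27.55%. If neutrophils express some of them, the dilution could be larger still. The sort for GFP is meant to remove such cells, but its purity is not given in the sources used here. For the granule genes, maturation of leukaemia cells under brequinar cannot be told apart here from such cells.

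The second pattern is that macrophage, erythroid and Y-linked genes were higher together. Of 12 further marrow macrophage genes with at least 20 counts summed over the libraries 75.0% were higher (9 higher, 2 lower), and 12 of all 16 sought were, but only 57.1% (4 of 7) of those with at least 20 counts in the vehicle library, and the higher genes ran from the abundant Slc40a1 to Cd163 (0.465 and 5.94 CPM), against Stab1 at 6.08 and 2.41 CPM, which is weakly consistent with macrophages of the marrow, or their RNA, in the brequinar sort. Pooled counts of 4 Y-linked genes were 4.01-fold higher (interval 3.07 to 5.31; 69 and 260 counts), which is part of the pattern itself, so it cannot support cells or RNA with a Y chromosome from outside the leukaemia, and that source stays open. Leukaemia cells gaining macrophage genes stays open, as the median of 5 broad monocyte and macrophage genes was 0.03 and their high level in the vehicle library would hide a small gain. The sort for GFP is meant to remove host cells. Neither its purity nor the sex of the animals is given in the sources used here.

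The last pattern is that all 52 ribosomal protein genes had ratios below 0. Annotated transcript length is no sufficient reason. The 652 other abundant genes of 668 to 2632 bases had a median log2 ratio of 0.09 (interval 0.06 to 0.13). Lengths were those of the longest annotated transcript of each gene. The expressed transcripts can be shorter, so a loss of short transcripts in the brequinar library stays open. A trend with these lengths and with GC content accounts for part at most. The list's median stayed at -0.51 (interval -0.63 to -0.44) after correction for both, against -0.67 before. No biological explanation was tested for this pattern.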
